A study of Mus musculus with 12 samples.

How the data were processed

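RNA-seq was performed on cochlear epithelium, the lining of the auditory part of the inner ear, of mouse embryos at embryonic day 16.5. Per the labels' protocols, the epithelium was dissected by hand and freed of surrounding mesenchyme with collagenase, both cochleae of an embryo were pooled, and polyA RNA was made into libraries with a directional kit. Each of 6 embryos gave 2 libraries, 12 libraries in all. There were 3 wild-type embryos (control) and 3 embryos lacking Esrp1, an epithelial splicing regulator (Esrp1 knockout). The individual embryos were the biological replicates, so that p-values of the gene tests rest on the spread between embryos.

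The read counts analysed were deposited by the authors as 1 column per embryo, in which the 2 libraries of that embryo stand together, with the embryo number that the labels give. Per the file headers, the counts are reads per RefSeq transcript, with no normalisation. The deposited table also held FPKM per embryo, which per the file headers the authors scaled by transcript length and library size. Its log2 fold changes with their p-values and FDR come, per the file headers, from an edgeR comparison of knockout with control made by the authors over transcript rows. The submitters' processing notes name edgeR and the genome build mm10. The aligner and the read counter are not given in the sources used here. A further 14 columns were not used here.

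The table had 28644 transcript rows for 22869 gene symbols, and 3705 symbols had more than 1 row. Rows of a gene count largely the same reads, so each gene was represented by its row with the most reads over the 6 embryos. Of the symbols, 4361 had no read in any embryo. No row lacked a gene name. Differently named genes with identical counts formed 14 groups of at least 60 reads, among them C1qtnf5 and Mfrp, whose reads cannot be told apart here. Coordinates were taken from RefSeq on GRCm38, the assembly that mm10 represents, in which 14707 of the 14717 genes tested had a position. Summed over genes, the depth was 16411205, 21568516 and 18472463 reads in control embryos 1, 2 and 3, and 12547301, 18473139 and 15830641 reads in knockout embryos 1, 2 and 3.

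Genes with enough reads were kept with filterByExpr (minimum count 10) in edgeR 4.0.16 under R 4.3.3, and library sizes were scaled by TMM. Knockout was compared with control by edgeR's quasi-likelihood F test on the counts, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are knockout over control. Their standard errors were taken as the size of the log2 fold change over the square root of F. Levels are TMM-scaled CPM, given as mean ± SD of 3 embryos. For genes with few reads, the ratio of summed reads is given with its exact 95% interval. Read numbers and intervals cover counting error only.

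Gene lists, 32 in all, covered cochlear cell types, other tissues that a dissection can carry along, signalling pathways, splicing, stress and deafness genes. The 30 lists with at least 5 genes tested were compared with all other genes by limma 3.58.1's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and again with an estimated correlation. limma's fry tested each list by itself against no change, not against other genes. These list p-values are adjusted over the 30 lists. With the preset correlation, camera's p-value does not take in how far a list's genes vary together between embryos. A list's level in an embryo is the mean over its genes of log2 CPM less the mean of the 6 embryos. The list of mitochondrially encoded genes had 0 genes tested, and the list of sex-linked genes 3. The named genes are Esrp1, the 10 largest rises and 10 largest falls among genes past the threshold with separated groups and a mean CPM of at least 1 (clone and model names left out), up to 4 members past the threshold of each list or else the member with the smallest adjusted p, and 12 genes of interest (Esrp2, Fgfr2, Fgf10, Fgf20, Otx2, Atoh1, Pou4f3, Sox2, Kcnq1, Epcam, Cdh1 and Vim). Groups, tests, lists and this rule were fixed before the data were examined. A gene that the rule takes is not reported here. Other genes in the text were chosen after their values were seen and are named as such.

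Shares of transcript rows were compared for 1711 pairs of rows in 1188 genes. For each pair, the reads of the gene's main row less those of a further row were taken as a share of the main row. Pairs needed at least 60 such reads over 6 embryos and no negative difference in any embryo. Their log2 odds were tested with limma. The difference is net, since reads held by the further row alone cancel against it. Exchanges of exons that leave it unchanged would be missed. This test was chosen after the table was seen. Each test was checked on counts simulated from the 6 embryos. In the gene test over 14586 genes, 63 of 100 genes changed by 2-fold and 96 of 100 changed by 4-fold were recovered, with 7 false calls. The changed genes were drawn from those with a mean CPM of at least 5, so recovery of genes with fewer reads was not checked. Each gene was simulated by itself, without differences between embryos that many genes share. The list test called the 1 changed list and 0 of 40 unchanged lists. Its simulated genes varied independently, so this check does not cover correlation between the genes of a list. The test of row shares recovered 40 of 40 changed pairs with 2 false calls. Only pairs with many such reads were changed, by 4-fold odds, with counting error but no variation between embryos. Recovery of smaller or noisier changes in shares was therefore not checked.

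The alternatives were RLE size factors, DESeq2 1.42.0, edgeR's exact test, limma-voom, other count filters, a minimum fold of 2, a block for the embryo number, each embryo left out in turn and genes of other tissues removed. Added after the data were seen were a test of all transcript rows, limma on log2(FPKM + 1) for genes with a mean FPKM of at least 0.5, Xist as a covariate, genes off chromosomes X and Y, list tests with 1 gene per group of identical counts, and fits without the embryos that stood apart in sex-linked or immediate early genes. Tables were read with pandas 2.3.3 under Python 3.11.15 and plots drawn with matplotlib 3.10.9.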

Results

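Transcript abundance was measured in the cochlear epithelium of 3 control and 3 Esrp1 knockout mouse embryos at embryonic day 16.5. ESRP1 is an RNA-binding protein that sets epithelial splicing patterns, and the comparison asks which genes differ in the developing cochlea when it is missing. Between 12547301 and 21568516 reads per embryo fell on genes, and 14717 genes were tested.

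Esrp1 itself (chromosome 4, 11331933 to 11386783, mm10) fell in the knockout. Its level was 139 ± 50.9 CPM in controls and 33.5 ± 5.98 CPM in knockouts (SD, n = 3 each), which is 24.1% of control. Every knockout embryo (27.2 to 39.1 CPM) lay below every control embryo (102 to 197 CPM). The log2 fold change was -2.05 ± 0.26 (SE, adjusted p = 0.0354, edgeR's quasi-likelihood test). A two-sided exact permutation test of 3 against 3 embryos gave p = 0.10, the smallest it can give. Leaving out control 3 or any of knockouts 1, 2 and 3 moved the adjusted p to between 0.122 and 0.158, with log2 fold changes of -2.18 to -1.93. Esrp2, the related splicing regulator, had a log2 fold change of 0.23 (adjusted p = 0.994).

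Genes of the stria vascularis, the lateral wall epithelium that secretes the potassium-rich endolymph, showed the 3 largest falls among genes past the threshold with separated groups and a mean CPM of at least 1. Bsnd, which encodes the chloride channel subunit barttin, fell from 193 reads over the 3 controls to 2 reads over the 3 knockouts, a ratio of 79.7 (95% interval 21.8 to 663, adjusted p = 0.0354). Kcne1, the beta subunit of the strial potassium channel, fell by 4.67 on the log2 scale (654 against 22 reads, ratio 24.6, 95% interval 16.1 to 39.5, adjusted p = 0.0137). Esrrb, a nuclear receptor needed in strial marginal cells, fell by 3.98, from 102 ± 36.1 to 6.48 ± 3.21 CPM (adjusted p = 0.0137). The genes that fell also included Epyc, a small proteoglycan (577 ± 30.9 to 209 ± 30.7 CPM), the growth factor Igf1 (376 ± 76.3 to 140 ± 22.7 CPM), the aminopeptidase gene Enpep, the protocadherin gene Pcdh20, the sialyltransferase gene St8sia3 and Nipal1, a magnesium transporter family member. Their log2 fold changes ranged from -3.87 for Nipal1 to -1.43 for Igf1. Nipal1 had 187 reads over the controls and 10 over the knockouts (ratio 15.45, 95% interval 8.22 to 32.75).

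The largest rise among the genes past the threshold was that of Tmem72 (chromosome 6, 116691539 to 116716982), which encodes a membrane protein, from 15 reads over the controls to 555 over the knockouts (ratio 44.8, 95% interval 26.9 to 80.6, adjusted p = 0.0137). Tmem27, a collectrin gene on chromosome X, rose by 2.94 on the log2 scale. C1qtnf5 and Mfrp, which overlap on chromosome 9 and share their reads, rose by 2.68. The neighbouring claudin genes Cldn22 and Cldn24 on chromosome 8, members of the tight junction family, rose by 2.29 and 2.18 (47824482 to 47825475 and 47822143 to 47822805). The nucleoporin-like gene Nup62cl on chromosome X rose by 2.08, the acyl-CoA synthetase gene Acsm4 by 1.94, and Naip1, an inflammasome sensor family member, by 1.69. Slc26a7, an anion exchanger of Reissner's membrane, rose from 24.3 ± 4.95 to 78.2 ± 20.4 CPM. This gene lies on chromosome 4 (14502430 to 14621946), as does the deleted Esrp1 (11331933 to 11386783). Whether that nearness plays a part was not tested.

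**Figure D1:**
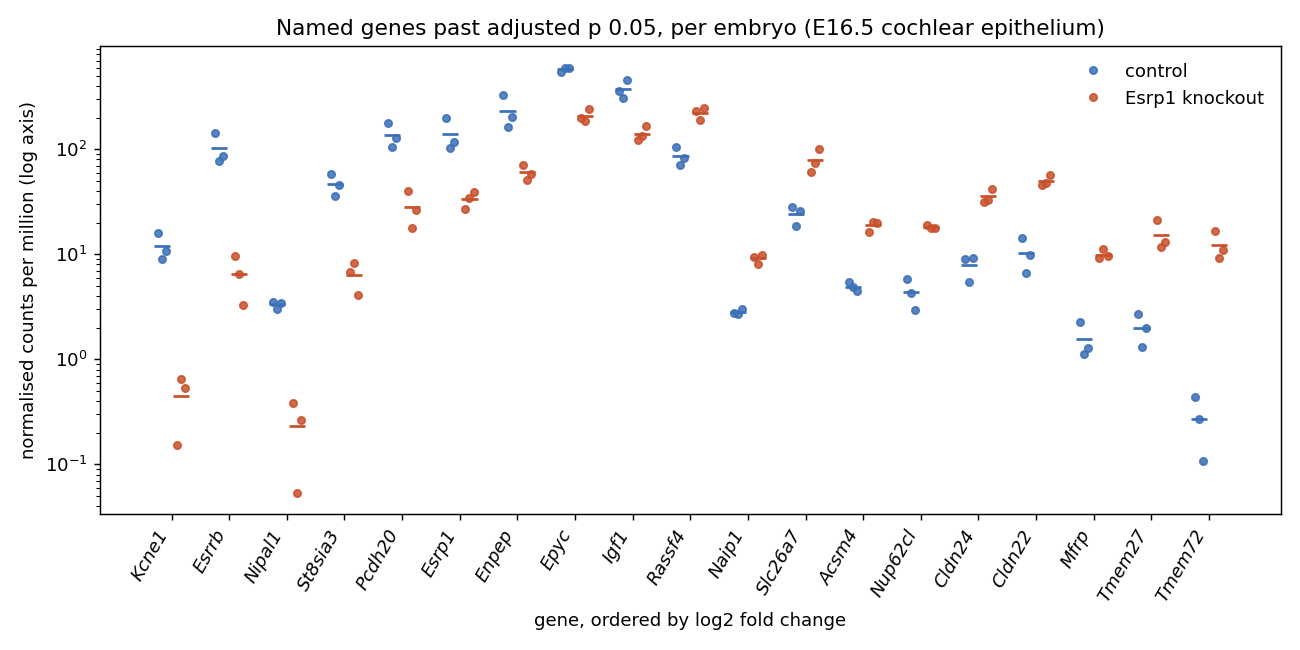
Normalised read counts as CPM (log axis) of genes past an adjusted p of 0.05 that the text names, one point per embryo and a short line at each group mean, ordered by log2 fold change. In each gene the 3 knockout embryos lie on one side of the 3 control embryos. Bsnd is left out because 2 knockout embryos had no read, and C1qtnf5 because it has the counts of Mfrp.

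In all, 22 genes changed (12 higher and 10 lower in the knockout, edgeR's quasi-likelihood test). Among them Rassf4 rose by 1.37 and was taken up after its value was seen. All 22 had separated groups, as had 9.84% of all genes tested, where chance gives 10%. At an unadjusted p under 0.05 were 702 of the 14717 genes, where chance gives 736. The authors' deposited table gave an FDR under 0.05 to the same 22 genes, among 222 transcript rows of 169 genes (123 rows higher, 99 lower). The count depended on single embryos: it was 30, 13 and 0 without control 1, 2 and 3, and 12, 0 and 4 without knockout 1, 2 and 3. DESeq2 called 167 genes, with all 22 among them.

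The embryos differed in sex-linked genes. Knockouts 2 and 3 had 94.97 and 81.87 CPM of the Y-linked Ddx3y and 0.27 and 0.20 CPM of Xist, the RNA of the inactive X, while knockout 1 and the 3 controls had under 1 CPM of Ddx3y and 1098 to 1808 CPM of Xist. Ddx3y had a log2 fold change of 6.21 (adjusted p = 0.216). Of the 3 sex-linked genes tested in edgeR 0 passed over all genes and 2 adjusted over the list alone. DESeq2, run without edgeR's count filter, called 3 sex-linked genes over all genes, of which only Ddx3y was also tested in edgeR. With Xist as a covariate 5 genes were called, of which 1 was among the 22. With knockouts 2 and 3 left out 0 genes were called, in a fit where the spread came from the controls alone and the lone knockout was assumed to vary like them. In both fits all 22 kept their sign, at a median of 0.956 and 0.953 of their log2 fold change, while the standard errors grew by a median factor of 1.33 and 1.42 and 3 and 2 residual degrees of freedom were left instead of 4. Esrp1 had -2.05 ± 0.26 with all embryos, -2.36 ± 0.43 with Xist and -2.35 ± 0.46 without knockouts 2 and 3 (SE). Both fits rest largely on knockout 1 against the controls. All 22 genes had been called with knockout 1 included and had separated groups, so the kept signs were mostly given in advance. Neither the lower counts nor the kept signs therefore show whether the changes depend on sex. The immediate early genes also set some embryos apart, with Fos at 153 CPM in control 1 and 64.6 CPM in knockout 1 against 1.00 to 7.28 CPM in the other 4. Without these 2 embryos 159 genes were called, all 22 among them. Controls 2 and 3, with Xist and low Ddx3y, then stood against knockouts 2 and 3, with the reverse. Sex and genotype therefore cannot be told apart in that fit. The same holds for every gene or list test without both embryos numbered 1 or without knockout 1.

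Counts of list members are those of edgeR's test unless DESeq2 is named. Among 18 strial marginal cell genes tested, 3 fell (Kcne1, Esrrb and Bsnd, the same in DESeq2) and 0 rose, with the same 3 when adjusted over the list alone. The other 15 did not pass, including the potassium channel gene Kcnq1 at -0.91 (adjusted p = 0.808). The list was lower by camera with a preset correlation (adjusted p = 0.00477), and had an adjusted p = 0.612 with an estimated correlation. Its median log2 fold change was -0.14 and its mean -0.84. The call was lost without control 1 (adjusted p = 0.274), knockout 2 (0.0509) or both embryos numbered 1 (0.101). The same 3 genes were those that fell among 56 deafness genes (adjusted p = 0.000125, and adjusted p = 0.612 with an estimated correlation), of which 5 fell and 1 rose adjusted over the list alone. DESeq2 had 5 lower and 2 higher over all genes. Without control 1 (adjusted p = 0.0837) or both embryos numbered 1 (0.0992) the list call was lost. The pigment cell list, whose cells form the intermediate layer of the stria, was lower by camera (adjusted p = 0.000125, and adjusted p = 0.612 with an estimated correlation), with 9 of 11 members negative, a median of -0.48 and 0 members past the gene test, also adjusted over the list alone. Its smallest adjusted p was that of the melanosome transporter gene Slc45a2 (-1.24, adjusted p = 0.628). With Xist as a covariate the strial and pigment cell lists had adjusted p = 0.550 and 0.777 by camera. That fit rests largely on knockout 1 against the controls, so the lost calls do not show whether these falls depend on sex. Kcne1, Esrrb and Bsnd had log2 fold changes of -6.22, -3.32 and -4.22 with Xist as a covariate.

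Genes of Reissner's membrane and the non-sensory roof, the thin epithelium that closes the cochlear duct, had mostly positive log2 fold changes (9 of 13 tested). Of these 13, Slc26a7 rose and Enpep fell, adjusted over the list alone 7 rose and 2 fell, and in DESeq2 over all genes 7 rose and 1 fell. Camera called the list higher (adjusted p = 0.000125, and adjusted p = 0.612 with an estimated correlation), with a median log2 fold change of 1.01. Otx2, a homeobox gene of the roof, had 37.7 ± 17.5 CPM in controls and 75.9 ± 5.34 CPM in knockouts (log2 fold change 1.01, adjusted p = 0.494). Oc90, an otoconial matrix gene also on the vestibular list, had a log2 fold change of 1.10 (adjusted p = 0.377). Chosen after their values were seen, Vmo1 (2.24, adjusted p = 0.0675), Wnt4 (1.27, adjusted p = 0.196) and the homeobox genes Dlx5 (3.30, adjusted p = 0.107) and Dlx6 (4.52, adjusted p = 0.123) passed over the list alone. With Xist as a covariate the list had an adjusted p = 0.145.

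**Figure D2:**
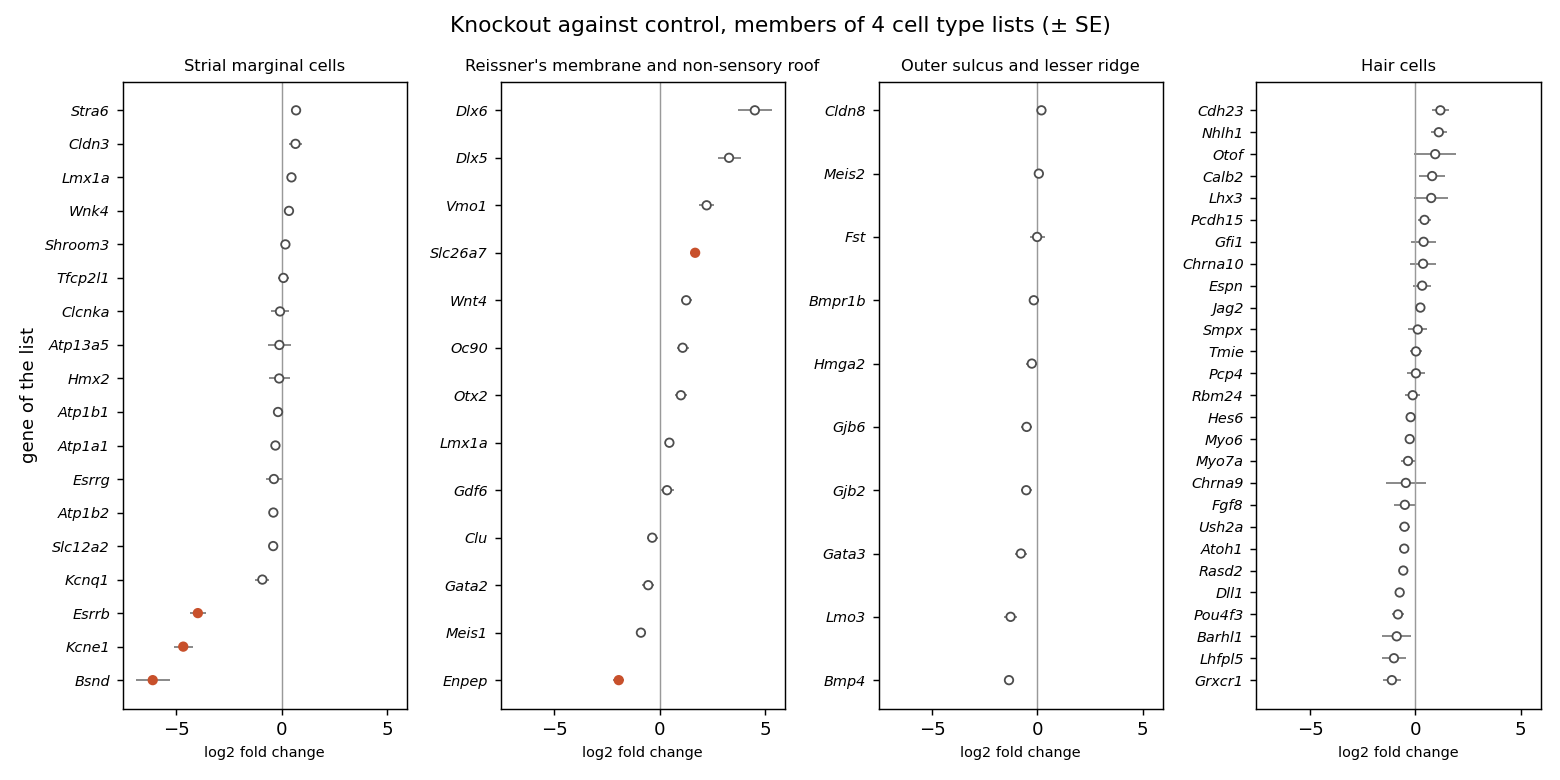
Log2 fold change of knockout over control (horizontal axis, ± SE) for each gene tested in the lists of strial marginal cells, Reissner's membrane and non-sensory roof, outer sulcus and lesser ridge, and hair cells. Filled points are past an adjusted p of 0.05: Bsnd, Kcne1, Esrrb and Enpep below 0 and Slc26a7 above 0.

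In the floor of the duct, Epyc fell within the list of Kölliker's organ and tectorial membrane genes, the only one of 19 tested to pass edgeR's test over all genes, while 2 fell and 1 rose adjusted over the list alone and also in DESeq2 over all genes (camera lower, adjusted p = 0.0272, and adjusted p = 0.625 with an estimated correlation). That call was lost without control 1 (adjusted p = 0.962), knockout 1 (0.449) or knockout 2 (0.0509), the direction turned without both embryos numbered 1 (0.0737), and knockouts 2 and 3 (levels -0.09 and 0.14) lay within the controls (-0.18 to 0.33). Of 10 outer sulcus and lesser ridge genes 0 passed in edgeR over all genes, while 2 fell adjusted over the list alone and also in DESeq2 over all genes, with Bmp4, a signal of the lateral duct, at 99.0 ± 11.3 and 38.7 ± 11.8 CPM (log2 fold change -1.35, adjusted p = 0.107). That list was lower by camera (adjusted p = 0.000172, and adjusted p = 0.612 with an estimated correlation), but not without control 1 (0.0648) or both embryos numbered 1 (0.578). Knockout 1 stood apart in it, at a level of -0.71, while knockouts 2 and 3 were at -0.17 and 0.12 beside controls at -0.01 to 0.57. Hair cell genes had mixed signs, 13 of 27 positive. Camera called the list lower (adjusted p = 0.00646, and adjusted p = 0.621 with an estimated correlation), while its level in knockout 1 (0.65) was above that of each control (-0.06 to 0.21) and those of knockouts 2 and 3 (both -0.50) were below. The call was lost without control 1 (adjusted p = 0.152), knockout 2 (0.401) or knockout 3 (0.133), kept without both embryos numbered 1 (5.9e-05), and the direction turned with Xist as a covariate (0.0785). Supporting cell and prosensory genes were lower by camera (22 tested, adjusted p = 0.0210, and adjusted p = 0.612 with an estimated correlation), but not without control 1 (0.0673), knockout 1 (0.195) or both embryos numbered 1 (0.649). In the hair cell and supporting cell lists 0 members passed over all genes or adjusted over the list alone. The hair cell transcription factors Atoh1 and Pou4f3 had log2 fold changes of -0.53 (adjusted p = 0.994) and -0.83 (adjusted p = 0.676), Rasd2 had -0.57 (adjusted p = 0.277), the prosensory factor Sox2 had -0.08 (adjusted p = 0.994) and the Notch effector Hes5 had -1.39 (adjusted p = 0.512).

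Epithelial and mesenchymal programmes were not called with all 6 embryos. Of 32 epithelial identity genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.431, with a median of 0.11, a mean of -0.01 and a test sign of up), with the adhesion genes Cdh1 at -0.33 and Epcam at 0.16 (both adjusted p = 0.994) and the epithelial transcription factor Grhl1 at -1.28 (adjusted p = 0.494). Of 16 mesenchymal genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.0660), with the intermediate filament gene Vim at 0.20 (adjusted p = 0.994) and the smooth muscle actin gene Acta2 at 1.12 (adjusted p = 0.589). Both lists were called higher with some embryos left out: the epithelial list without control 1 (adjusted p = 6.5e-09) or both embryos numbered 1 (1.5e-08), and the mesenchymal list without control 2 (0.0198), control 3 (0.00919) or knockout 1 (0.0124). Of 16 endolymph ion transport genes 0 passed either way (camera adjusted p = 0.103), with the sodium channel subunit gene Scnn1g at -1.49 (adjusted p = 0.712), and the list passed without control 2 (0.0188). Of 6 vestibular and otoconial genes 0 passed in edgeR over all genes, while Oc90 passed adjusted over the list alone and in DESeq2 (camera adjusted p = 0.0533, 0.000401 without control 1 and 3.0e-05 without both embryos numbered 1). Of 26 cell cycle genes 0 passed either way (camera adjusted p = 0.103), with the mitotic kinase gene Plk1 at 0.39 (adjusted p = 0.678), and the list passed without control 2 (0.00203).

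No member of the signalling lists passed edgeR's test over all genes. DESeq2 called 3 lower and 1 higher of the BMP and TGF-beta list, 2 lower and 1 higher of the Wnt list and 3 higher of the retinoic acid list. BMP and TGF-beta genes were lower by camera (23 tested, adjusted p = 0.00477, and adjusted p = 0.612 with an estimated correlation), with 4 lower and 2 higher adjusted over the list alone. Knockout 1 set this list apart, at a level of -0.35 against 0.01 and 0.03 in knockouts 2 and 3 and -0.02 to 0.21 in the controls, and the call was lost without knockout 1 (adjusted p = 0.0732) or both embryos numbered 1 (0.262). Retinoic acid genes were higher by camera (13 tested, adjusted p = 0.00241, and adjusted p = 0.612 with an estimated correlation), with knockout 1 apart at 0.66 against -0.08 and -0.17 in knockouts 2 and 3 and -0.30 to -0.06 in the controls. Without knockout 1 that call was lost (adjusted p = 0.0732), but it was kept without both embryos numbered 1 (0.0456). The list had 5 members higher adjusted over the list alone and Rdh10, a retinoid synthesis enzyme gene, at 0.82 (adjusted p = 0.224). Notch genes were lower (16 tested, adjusted p = 0.0272, and adjusted p = 0.612 with an estimated correlation), with 0 adjusted over the list alone, but not without control 1 (0.277), knockout 1 (0.111), knockout 2 (0.0509) or both embryos numbered 1 (0.932). Wnt genes were not called (28 tested, adjusted p = 0.0684, 2 lower and 1 higher adjusted over the list alone), with the secreted inhibitor gene Frzb at -0.93 (adjusted p = 0.166), and passed without control 2 (0.0291) or knockout 3 (0.0282). Neither were FGF genes (24 tested, adjusted p = 0.263), with Fgfr3 at -0.79 (adjusted p = 0.541), nor Hedgehog genes (11 tested, adjusted p = 0.559, median -0.10), with Gas1 at 0.64 (adjusted p = 0.687), each with 0 members adjusted over the list alone. The FGF list passed without knockout 1 (adjusted p = 0.0472) or both embryos numbered 1 (0.00152). Fgfr2, a receptor whose exon choice ESRP1 sets, had 194 ± 45.7 and 156 ± 30.6 CPM (log2 fold change -0.31, adjusted p = 0.994). The FGF ligand genes Fgf10 and Fgf20 had -0.10 (adjusted p = 0.994) and 0.72 (adjusted p = 0.906).

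Known ESRP splicing targets were lower in total abundance by camera (30 tested, median -0.09, adjusted p = 0.00775, and adjusted p = 0.621 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone. Knockout 1 alone lay low, at a level of -0.26, while knockouts 2 and 3 were at -0.00017 and 0.04 beside controls at 0.0048 to 0.18. The call was lost without control 1 (adjusted p = 0.306) or knockout 1 (0.507), and without both embryos numbered 1 the direction turned (0.578). Splicing regulators were not called (25 tested, adjusted p = 0.387, 0 adjusted over the list alone), with the smallest gene p at Khdrbs3 (0.15, adjusted p = 0.994), and passed without control 1 (0.0427). Of 1711 pairs of transcript rows tested with limma for a changed share within a gene, 0 passed, against 91 at an unadjusted p under 0.05 where chance gives 86. The smallest adjusted p was 0.301, for Epb4.1l5, a cytoskeletal adaptor gene. Its main row's reads less those of a further row made up 51.3 ± 2.93% of the main row in controls and 69.4 ± 1.5% in knockouts (SD, n = 3 each). Whole-transcript counts do not resolve the alternative exons of Fgfr2.

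Markers of other tissues that a dissection can carry along were compared in the same way. Macrophage and leukocyte genes were higher by camera (14 tested, 13 positive, adjusted p = 0.000724, and adjusted p = 0.621 with an estimated correlation), with C1qa, a complement gene, at 0.57 (adjusted p = 0.994). This call came from control 1, at a level of -1.06 against 0.14 and 0.22 in controls 2 and 3 and 0.10 to 0.34 in the knockouts, and was lost without it (adjusted p = 0.646), while the direction turned without both embryos numbered 1 (0.825). Erythroid genes were lower by camera (9 of 9 negative, adjusted p = 0.0160, and adjusted p = 0.621 with an estimated correlation), with the embryonic globin gene Hbb-y at -0.64 (adjusted p = 0.994), but not without control 2 (0.869) or knockout 2 (0.482), and kept without both embryos numbered 1 (4.6e-05). The 9 are 7 distinct measurements, since Hba-a1 and Hba-a2 have identical counts, as do Hbb-b1 and Hbb-b2 (named after their values were seen), and with 1 gene of each pair the list had an adjusted p = 0.0206. Immediate early and stress genes were lower by camera (20 tested, adjusted p = 0.0272, and adjusted p = 0.646 with an estimated correlation), with Klf4 at 0.30 (adjusted p = 0.994). Control 1 set this call, at a level of 1.41 against -0.33 and -0.39 in controls 2 and 3 and 0.58, -0.55 and -0.72 in the knockouts. Without control 1 the direction turned (adjusted p = 0.284), and the call was also lost without knockout 2 (0.135), knockout 3 or both embryos numbered 1 (0.0737). Not called were periotic mesenchyme (18 tested, adjusted p = 0.103, Postn at 0.94), cartilage (8 tested, adjusted p = 0.551, Matn1 at 1.18), neurons (20 tested, adjusted p = 0.222, Ntrk2 at 0.52), Schwann cells (11 tested, adjusted p = 0.559, Cdh19 at -1.09), endothelium (14 tested, adjusted p = 0.507, Emcn at -0.34) and muscle (5 tested, adjusted p = 0.30, Acta1 at 0.29). The neuronal list had a median of -0.12 and a mean of -0.05 with a test sign of up. With 1 embryo left out, periotic mesenchyme passed without control 2 (adjusted p = 0.0226), control 3 (0.000338) or knockout 3 (0.0184), cartilage without knockout 3 (0.0282), neurons without control 1, 2 or 3 (0.000401, 1.4e-06 and 0.0374), endothelium without control 1, control 2 or knockout 3 (0.0322, 0.0488 and 0.0282) and muscle without control 1 or knockout 3 (0.00140 and 0.00114). The direction turned for neurons without control 1 and for endothelium without control 2 or knockout 3. Without both embryos numbered 1 endothelium passed (0.00505), as did neurons in the turned direction (0.00152). In these 9 lists 0 members passed over all genes or adjusted over the list alone.

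In total camera called 15 of the 30 lists (3 higher, 12 lower), against 0 with an estimated correlation and 0 by fry's directional test, which asks for change in a list by itself. Fry's test of change in either direction, likewise without other genes for comparison, passed for the lists of Kölliker's organ (adjusted p = 0.00969), Reissner's membrane (0.000885), strial marginal cells (0.000268), BMP and TGF-beta (0.0410) and deafness genes (0.000399). Without control 1, 2 and 3 in turn, 5, 14 and 15 of the 15 calls were kept, and without knockout 1, 2 and 3, 9, 9 and 13. Of the 15 lists called, 13 lost the call with at least 1 embryo left out, the exceptions being Reissner's membrane and pigment cells. The pigment cell level was 0.13 in knockout 1 but -0.54 and -0.45 in knockouts 2 and 3, beside controls at 0.18 to 0.44. Its fall thus lay mostly in the 2 knockouts that differed in sex-linked genes. The level of Reissner's membrane was 0.46, 0.35 and 0.47 in knockouts 1, 2 and 3, beside controls at -0.86 to 0.08. Of the 15 not called, 13 passed with at least 1 embryo left out.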

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

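Tests that used Xist as a covariate, left out knockouts 2 and 3 or both embryos numbered 1, tested all transcript rows, used FPKM, dropped chromosomes X and Y or kept 1 gene per group of identical counts were chosen after the data were seen. The 22 genes remained with RLE size factors (22 called), all transcript rows (22), the removal of other-tissue genes (22) and a 2-fold minimum (22). limma-voom called 22 with 21 shared, FPKM 24 with 17 shared, no filter 31, a mean CPM of at least 5 20, and genes off X and Y 20. DESeq2 called 167 (106 higher, 61 lower) and the exact test 168. Leaving out 1 embryo gave 0 to 30 genes, the Xist covariate 5, leaving out knockouts 2 and 3 0 (the lone knockout assumed to vary like the controls), and leaving out both embryos numbered 1 159. The cause of these differences was not tested. In fits without knockout 1 or both embryos numbered 1, every knockout left had high Ddx3y and no control had. Sex and genotype cannot be told apart there. Esrp1 stayed negative in 20 alternatives (-2.36 to -1.59), with adjusted p under 0.05 in 13: leaving out 1 embryo gave -2.23 to -1.71, the Xist covariate -2.36 and leaving out knockouts 2 and 3 -2.35. Of 393 alternative values for the other 20 named genes called, 255 kept the call, 138 lost it and 0 changed sign. Of 705 for named genes not called, 24 passed.

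Embryos of a number share the first part of a code in the labels whose meaning is not stated. Their deviations from the group means correlated at 0.077, 0.177 and 0.029, and not every embryo correlated best with its own number. With the number as a block 6 genes were called (5 of the 22), and Esrp1 had -1.996 (adjusted p = 0.134). Camera then called 14 lists, 13 of them among the 15 called without the block. Kölliker's organ was among those that lost the call (adjusted p = 0.0600), and periotic mesenchyme gained one (0.0387).

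Lists called were 15, against 16 with RLE, the same 15 with 1 gene per group of identical counts, 9 to 22 with 1 embryo left out, 5 with the Xist covariate, 7 without knockouts 2 and 3, 11 without both embryos numbered 1, 0 with an estimated correlation and 0 by fry. Directions turned, as adjusted p, for hair cells (Xist 0.0785, without knockouts 2 and 3 0.0800), erythroid genes (0.867 and 0.778) and immediate early genes (0.602 and 0.607). Without both embryos numbered 1 they turned for Kölliker's organ (0.0737), neurons (0.00152), leukocytes (0.825) and ESRP targets (0.578). Leaving out 1 embryo turned neurons (without control 1, 0.000401, range 1.43e-06 to 0.586), endothelium (without control 2, 0.0488, without knockout 3, 0.0282, range to 0.217) and immediate early genes (without control 1, 0.284, range from 8.67e-06). The cause was not tested. Counts of each library alone could not be run, since both libraries of an embryo stand in 1 column, and the pseudocount and low-value filters planned for a table without counts were not run.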

Other observations

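The mast cell and choroid plexus lists, and the tests of embryo sex, choroid plexus tissue and lateral wall share, were chosen after the result was seen.

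Mast cell genes were looked at because some of them had been seen with positive values, so a test of their list would not be independent. Over all genes 0 passed in edgeR and 5 in DESeq2. Of 12 on the list 7 were tested and 7 had positive log2 fold changes, with 5 separated between the groups. The tryptase gene Tpsb2 had 6.96 ± 2.26 and 26.4 ± 10.3 CPM (log2 fold change 1.92, adjusted p = 0.132), the chymase gene Cma1 had 7.56 ± 3.31 and 26.3 ± 11.2 CPM (1.79, adjusted p = 0.241) and the histidine decarboxylase gene Hdc had 2.71 ± 0.80 and 8.36 ± 2.36 CPM (1.62, adjusted p = 0.164). Cpa3, a mast cell peptidase gene, overlapped between the groups (1.38, adjusted p = 0.570), and Kit, which is also on the pigment cell list, had 0.07 (adjusted p = 0.994).

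The rise of Tmem72 and Mfrp raised the question of brain tissue, since choroid plexus also makes both. A choroid plexus list of 18 genes, 14 of them tested and 3 also on other lists, was made after this rise was seen, and over all genes 2 members (Tmem72 and Mfrp) passed in edgeR and 3 in DESeq2, with Otx2 (1.00, adjusted p = 0.0475). Of the 14, 11 had positive log2 fold changes, with a median of 0.40. Choroid plexus tissue would bring Ttr, its most abundant transcript, and Tmem72 in a fixed ratio. The rise of Ttr over that of Tmem72 was 8.11 in knockout 1 but 1.14 and 1.06 in knockouts 2 and 3, a 7.68-fold range, which argues against this tissue as the whole cause in the 3 embryos. A part of the Ttr in knockout 1 (146 CPM) may still come from it, and expression within the cochlear roof stays an open hypothesis.

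For the fall of Kcne1, Esrrb and Bsnd, a smaller share of lateral wall in the knockout samples was a candidate explanation. All 11 pigment cell genes, taken as marks of the same wall, fell short of the change of Esrrb (-3.98) by more than 2 standard errors of each. Their median was -0.48 and the lowest was -1.25 for Mlana. The pigment cell genes, 9 of 11 of them negative, thus changed less than Esrrb. Esrrb was taken up as one of the largest falls, so this shortfall was largely given in advance. Pigment cell genes also do not mark the wall's epithelium, and Kit is also on the mast cell list. A smaller share of that epithelium need not lower them, so they do not decide this explanation. Whether marginal cells were missing or present without Kcne1, Esrrb and Bsnd was not tested and stays open, as does the genotype as the cause.

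Of the 10 ways to split the 6 embryos into 3 and 3, 1 gave as many genes as the real one, namely the real one itself (22 genes, highest other 0). At an unadjusted p under 0.05 the real split had 702 genes and the others 146 to 1583, with 3 of them above 702. For lists, 3 of 10 splits gave as many (15 in the real split, highest other 19), and for pairs of transcript rows 10 of 10 (0 and 0). With 10 splits no share under 0.05 can be had. The sex of the embryos could contribute to the 22 genes, since knockouts 2 and 3 had 94.97 and 81.87 CPM of Ddx3y and the controls under 1 CPM. Among 7 autosomal genes called without knockout 1, that embryo, which had no Y-linked excess, showed a median of 0.854 of the shift of knockouts 2 and 3 and lay beyond the controls in 7 of 7. The 5 of these that are among the 22 had 0.76 to 1.34 of that shift, and the others, Adamts1 and Pgm5, had 0.45 and 0.29. The 5 genes among the 22 had also been called with knockout 1 included, so their shift in that embryo was partly given by that choice. As the comparison rests on 1 embryo, sex stays open.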
